A study of Rattus norvegicus with 6 samples.

How the data were processed

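RNA from laser-captured pancreatic duct glands of wild-type and HIP rats was measured by RNA sequencing in 6 libraries, 3 per group. Per the labels' protocols, glands were chosen by morphology, RNA was extracted with a kit for small samples and libraries were made with a kit for very low input. Per the submitters' processing notes, the tools were STAR, HTSeq, edgeR and limma and the genome build was rn5, without versions or order, and strandedness is not given in the sources used here. The authors deposited a table per library with 15679 gene symbols and a log2 value for each. The deposited log2 values were found to be CPM with a prior, since they sum to the same CPM total in each library after the prior is taken off and a gene without reads stands at -6.04, which fits a prior of 0.25 reads at the mean library. From these values whole reads were recovered for 100% of the entries in each library within a tolerance of 0.1 reads.

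Library totals ran from 15141136 to 17574683 reads, so that 1 read was worth 0.0569 to 0.066 CPM. The number of genes without a read was 2822 in WT26, 2488 in WT1, 672 in WT4, 2440 in HIP30, 2155 in HIP2 and 1837 in HIP3. The ribosomal RNA gene Rn45s took 2.10% to 4.88% of reads, and the 10 most abundant genes 4.85% to 7.68%. Limits for counts of 0 use 3 reads and cover counting error only, as the reads carry no molecular identifiers. Such a limit says nothing about transcripts lost before sequencing. Reads shared between paralogs, as among histone genes and the insulin genes Ins1 and Ins2, and overlapping genes could not be separated here.

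Groups were taken from the genotype labels. Before the data were examined, a quasi-likelihood test on counts had been planned, and because the deposited values are on a log2 scale the main test became limma 3.58.1 in R 4.3.3 with an intensity trend, on log2 of CPM plus 2 reads of an average library (0.121 CPM). Fold changes on this scale understate the change of low genes. TMM factors were computed from the recovered reads with trims of 30% of log ratios and 5% of levels, and lay between 0.933 and 1.09. Genes were tested if they had at least 10 reads at the median library (0.61 CPM) in 3 libraries and 15 reads in total, which left 12102. The symbols March1 and March2 each stand on several rows and their 4 rows were left out. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Of 15677 distinct symbols, 13387 match a current symbol of the GRCr8 annotation and 15240 a symbol or synonym; no coordinates were used.

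A set of 46 gene lists was fixed before the data were examined, covering duct gland biology, signalling, stress responses, markers of other cell types and RNA quality. The 44 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Camera compares a list with the other genes, while fry asks whether the genes of a list move on balance in 1 direction. Members were also adjusted over the list alone, which does not correct for the number of lists.

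Genes named in the text follow a rule fixed before the data were examined. Per direction, 12 genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups were to be named by size of change, and as none passed, all 12 places were filled by the lowest unadjusted p under the same limits. Up to 3 genes of each list with the lowest unadjusted p were added, with a set of duct, islet, acinar and proliferation markers always named where measured. The text prints values for part of the genes this rule gives, and some are not reported here.

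The steps were tested on simulated reads for the 12102 genes with 200 changed genes. At the spread of the real libraries, capped for the most variable genes, the comparison of HIP with wild type recovered 60% of genes changed 4-fold and 86% of genes changed 16-fold, with 10 calls among 11902 unchanged genes. Each gene was drawn independently, without differences between libraries that many genes share, so these shares need not hold for the real libraries. A simulated shift of -1 in the mitosis list was called by camera with both the preset and the estimated correlation (adjusted p = 2.21e-47 and 3.20e-03), with 0 of 43 other lists called. The genes of this list simulation were drawn independently too, with a common spread. It therefore cannot show how often camera calls unchanged lists when genes are correlated, as in the real libraries.

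Alternatives covered other scalings, filters and pseudocounts, limma-voom with and without sample quality weights, a batch term for the numbers 26 and 30 against 1 to 4, removal of acinar and dominant genes, and leaving out each library. That number series is read from the titles alone and is not stated to be a batch. Figures were drawn with matplotlib 3.10.9.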

Results

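The series compared the transcriptome of pancreatic duct glands between wild-type Sprague-Dawley rats and pre-diabetic HIP rats. Pancreatic duct glands are mucin-producing outpouchings in the wall of the larger pancreatic ducts. HIP rats carry a transgene for human islet amyloid polypeptide, which is driven in beta cells, and serve as a model of type 2 diabetes. Gland tissue was recognised by its morphology, isolated by laser capture microdissection and sequenced as total RNA. There were 3 wild-type libraries (WT26, WT1 and WT4) and 3 HIP libraries (HIP30, HIP2 and HIP3), each named by its group and the number in its title. The labels do not state that each library came from its own animal, so p-values measure the spread between these libraries, which may be technical. WT26 held 17574683 reads on the 15679 listed genes, WT1 17446411 and WT4 15821742. HIP30 held 15141136 reads, HIP2 16100854 and HIP3 16709668.

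The libraries carried transcripts of duct epithelium at high levels, given as CPM, reads scaled to a common library total. Krt19, a keratin of duct cells, stood at 4071 ± 2888 CPM (SD, n = 3) in the wild-type libraries and 1813 ± 431 CPM in the HIP libraries. Pdx1, a transcription factor of pancreatic development and beta cells, stood at 36.3 ± 2.61 and 35.2 ± 0.678 CPM. Neither gene passed limma's test (Benjamini-Hochberg adjusted p = 0.691 for Krt19 and 0.973 for Pdx1), and the sign of the Pdx1 difference, a log2 value of -0.04, turned with library totals in place of TMM factors.

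Transcripts of islet and acinar cells differed between libraries of the same group. Ins1, which encodes insulin, had no read in WT26 and HIP30, 69.0 CPM in WT1 and 102 CPM in HIP2, but 7761 CPM in WT4 and 3717 CPM in HIP3. Ins2, the other insulin gene, reached 3170 CPM in WT4 and 1234 CPM in HIP3, and rat Iapp, the amyloid polypeptide of beta cells, 274 and 60.2 CPM. Gcg, which encodes glucagon, had 11 reads in WT4, 2 in HIP3 and none in the other libraries. The acinar enzyme genes Prss1 and Cpa1 reached 8.45 and 2.92 CPM in WT4 and 7.41 and 11.2 CPM in HIP3, and stayed below 1 CPM in the other libraries. A count of 0 allows up to 0.179 CPM in WT26 and 0.182 CPM in HIP30, which covers counting error only. The group difference of Ins1 was -0.17 on the log2 scale with a standard error of 4.51 (limma, adjusted p = 0.993), and its sign turned when WT1, WT4 or HIP30 was left out, over a range of -4.35 to 3.94.

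**Figure D1:**
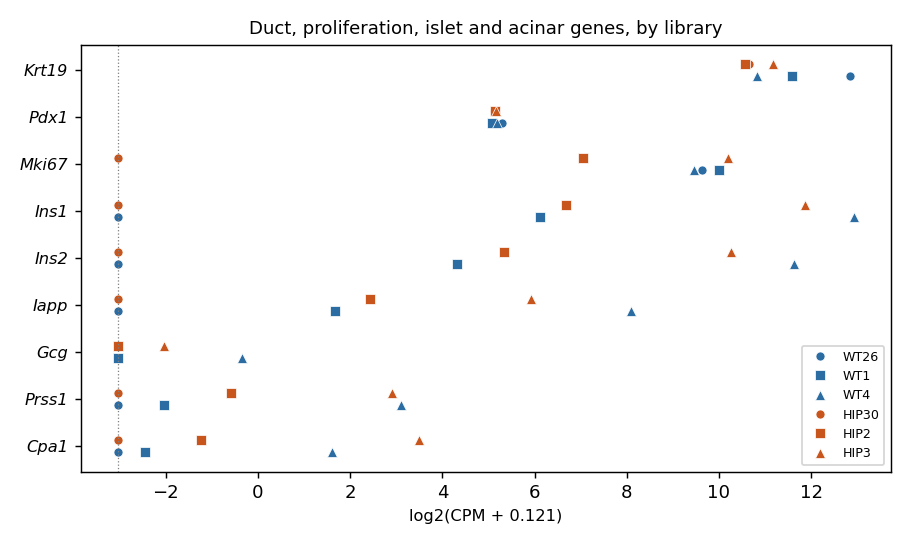
Level of 9 marker genes in each library, as log2 of CPM plus 0.121, where the dotted line marks 0 reads. Blue symbols are the 3 wild-type libraries and orange symbols the 3 HIP libraries. Ins1 stands at 0 reads in WT26 and HIP30 and at 7761 and 3717 CPM in WT4 and HIP3, while Mki67 stands at 0 reads in HIP30 alone.

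The comparison of HIP with wild-type glands asked whether the gland transcriptome differs where beta cells are under stress. No single gene passed the test over all genes, and the genes that follow were taken by rank. Slc26a9, an epithelial anion transporter, stood at 61.1 ± 17.6 CPM in HIP against 22.7 ± 5.74 CPM in wild type (SD, n = 3), a log2 difference of 1.42 with a standard error of 0.29. Clca1, a secreted regulator of chloride channels, stood at 1179 ± 30.04 against 509 ± 177 CPM, a log2 difference of 1.27 with a standard error of 0.27. Il33, an alarmin cytokine of epithelial cells, stood at 318 ± 64.5 against 83.8 ± 46.3 CPM, a log2 difference of 2.08 with a standard error of 0.42. Dpt, a matrix protein of fibroblasts, stood at 103 ± 17.1 against 216 ± 30.8 CPM, a log2 difference of -1.07 with a standard error of 0.20.

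The other genes higher in each of the 3 HIP libraries than in each of the 3 wild-type libraries, taken by lowest unadjusted p, were Hunk, Lefty2, Npas2, Slc7a11, Mmp12, Ccl3, Cldn2, Ccl7 and Ccl2. Cldn2, a pore-forming claudin of tight junctions, stood at 1175 ± 480.5 CPM in HIP against 429 ± 209 CPM in wild type. Slc7a11, the cystine transporter subunit, stood at 20.2 ± 8.64 against 5.59 ± 2.12 CPM. The chemokines Ccl2, Ccl3 and Ccl7 had log2 differences of 4.42, 3.71 and 3.90, with no read in WT26, and their HIP3 levels were 3.43, 1.10 and 0.858 CPM against highest wild-type levels of 2.92, 0.430 and 0.608 CPM. Mmp12, a macrophage elastase, had a log2 difference of 1.95, and Npas2, Hunk and Lefty2, a TGF-beta family antagonist, had differences of 0.98, 1.05 and 0.997.

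On the lower side stood, beside Dpt, the genes Fxyd6, Mmp2, Emp2, Ptn, Vav3, Mxra8, Ltbp1, Fos, Cryl1, Gpa33 and Olfml1. Mmp2, a gelatinase of stromal cells, stood at 26.7 ± 6.07 CPM in HIP against 56.2 ± 7.09 CPM in wild type, and Ltbp1, which binds latent TGF-beta in the matrix, at 13.9 ± 6.77 against 40.3 ± 8.96 CPM. Gpa33, an antigen of intestinal epithelium, had the largest difference of these 12 genes, -2.88 on the log2 scale with a standard error of 0.73. Fxyd6 differed by -1.85, Ptn, a heparin-binding growth factor, by -1.53, and Fos, an immediate early transcription factor, by -1.46.

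Each of these 24 genes missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.691). Of 12102 genes tested, 0 were higher and 0 lower in HIP by limma at an adjusted p of 0.05, and limma-voom also called 0. At an unadjusted p under 0.05 limma gave 792 genes, 398 higher and 394 lower, where 605.1 would be reached by chance, and limma-voom gave 914. The groups did not overlap in 9.54% of genes, where 3 against 3 libraries give 10% by chance. Without HIP3 the smallest adjusted p of limma went from 0.691 to 0.0882 and the unadjusted count to 1803, and without WT4 to 0.288 and 1605. In the other direction, the unadjusted count was 338 without WT26, 328 without WT1, 274 without HIP30 and 233 without HIP2.

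**Figure D2:**
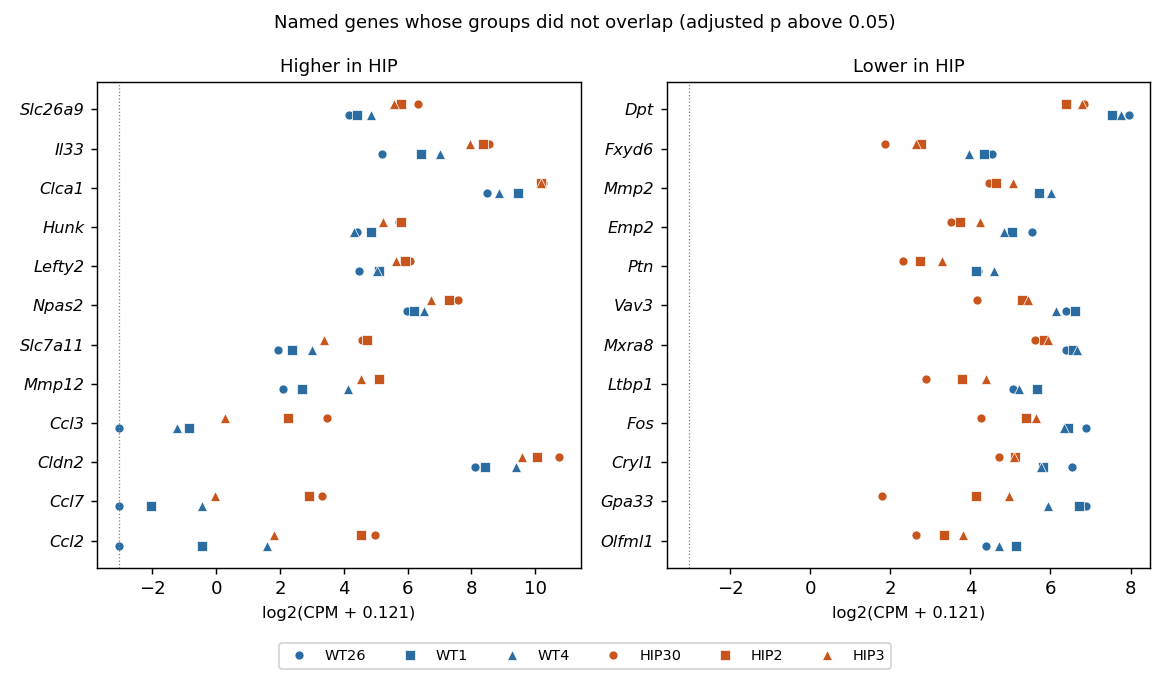
Level of the 24 genes named by rule in each library, as log2 of CPM plus 0.121, with genes higher in HIP on the left and lower on the right. Blue symbols are the 3 wild-type libraries, orange symbols the 3 HIP libraries and the dotted line marks 0 reads. The groups are apart for every gene shown, and none passed limma's test (adjusted p = 0.691).

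Lists of cell division genes passed camera in the lower direction with a preset correlation only, where adjusted p = 0.497 with an estimated correlation for each, and the difference lay in HIP30 and HIP2 and not in HIP3. All 31 tested mitosis genes had a negative difference, with a median of -3.49 on the log2 scale, and 21 of them had no read in HIP30. Against the wild-type mean, the median of the list was -7.93 in HIP30, -2.48 in HIP2 and 0.10 in HIP3, where the depth of the first value depends on the pseudocount. Mki67, the proliferation antigen, stood at 789, 1030 and 705 CPM in WT26, WT1 and WT4, and at 0, 133 and 1179 CPM in HIP30, HIP2 and HIP3. Kif23, a kinesin of cytokinesis, and Aurka, a mitotic kinase, stood at 149 ± 106 and 8.85 ± 6.46 CPM in HIP against 312.5 ± 90.5 and 21.3 ± 4.79 CPM in wild type. Of 30 genes of S phase replication 29 were negative, with a median of -0.97, and all 19 replication-dependent histone genes were negative, with a median of -1.59. The histone list had been fixed as a list of RNA quality and not of gland biology. Rrm2, a subunit of ribonucleotide reductase, stood at 4.002 ± 5.81 against 18.8 ± 7.27 CPM.

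The mitosis, S phase and histone lists passed limma's camera test with a preset correlation (Benjamini-Hochberg adjusted p = 1.44e-14, 1.40e-10 and 7.28e-07). None of them passed when the correlation between genes was estimated, where adjusted p = 0.497 with an estimated correlation for each. By number series, the mitosis median was -7.94 between HIP30 and WT26 and -1.16 between the libraries numbered 1 to 4. Without HIP30 the mean difference of the mitosis list went from -3.10 to -1.11, of the S phase list from -1.27 to -0.62 and of the histone list from -1.81 to -0.66, and without HIP3 to -4.70, -1.90 and -2.93. No member of these lists passed limma's test, adjusted over all genes or adjusted over the list alone.

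Lists of stromal genes passed camera in the lower direction with the preset correlation only, where adjusted p = 0.497 with an estimated correlation for each. All 20 tested genes of fibroblasts and stellate cells were negative, with a median of -0.70 on the log2 scale, and the list median against the wild-type mean was -1.17 in HIP30, -0.82 in HIP2 and -0.20 in HIP3, which lies above the value of -0.40 in WT26. Dcn, a small matrix proteoglycan, stood at 92.7 ± 40.3 CPM in HIP against 221 ± 71.1 CPM in wild type, and Serpinf1 at 24.2 ± 6.40 against 45.1 ± 8.21 CPM. Of 30 extracellular matrix genes 23 were negative, with a median of -0.71, and Lum and Col5a2 differed by -2.51 and -1.50, over ranges of -3.42 to -1.32 and -2.05 to -0.88 with libraries left out in turn. Of 17 genes of epithelial to mesenchymal transition 13 were negative, with a median of -0.79, among them Vim, the intermediate filament of mesenchymal cells, at 51.6 ± 7.62 against 79.4 ± 14.5 CPM, and S100a4, at 107 ± 69.1 against 283 ± 156.5 CPM. Of 17 smooth muscle and pericyte genes 14 were negative, with a median of -0.79, and Myl9, a myosin light chain, differed by -1.44, while Mylk, the kinase that acts on it, differed by 1.88. With libraries left out in turn Myl9 ran from -2.05 to -1.04 and Mylk from 0.94 to 2.66.

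These 4 lists passed camera with the preset correlation (limma, Benjamini-Hochberg adjusted p = 1.99e-08 for fibroblasts, 1.20e-03 for matrix, 4.34e-04 for transition and 2.80e-04 for smooth muscle). None passed otherwise, with adjusted p = 0.497 with an estimated correlation for each. The lists share genes, since 7 of the 20 fibroblast genes, 8 of the 30 matrix genes, 3 of the 17 transition genes and 3 of the 17 smooth muscle genes stand in another list too. Dpt passed limma's test adjusted over the list alone in the fibroblast list (adjusted p = 0.0131) and Mmp2 in the transition list (adjusted p = 0.0307), and neither passed over all genes (adjusted p = 0.691). Without HIP30 the mean difference of the matrix list went from -0.82 to -0.26, of the transition list from -0.86 to -0.40, of the smooth muscle list from -0.63 to -0.35 and of the fibroblast list from -0.87 to -0.55. Without HIP3 the means of the matrix and smooth muscle lists were -1.29 and -1.002, and without WT4 the smooth muscle mean was -0.42.

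Lists of acute phase, chemokine and myeloid genes passed camera in the higher direction with the preset correlation only, where adjusted p = 0.497, 0.508 and 0.664 with an estimated correlation. Of 13 regenerating and acute phase genes 11 were positive, with a median of 2.00 on the log2 scale. Reg3b, a secreted lectin of the regenerating family, had no read in WT26, 1.54 CPM in WT1 and 10.0 CPM in WT4, against 138, 68.5 and 7.72 CPM in HIP30, HIP2 and HIP3. C3, the central complement protein, stood at 1824 ± 183 CPM in HIP against 718 ± 700.2 CPM in wild type, and Spp1, the secreted phosphoprotein osteopontin, at 1323 ± 651 against 499 ± 283 CPM. Of 25 NF-kB targets and chemokines 20 were positive, with a median of 0.86, led by Ccl3, Ccl7 and Ccl2, and the list median against the wild-type mean was 1.18 in HIP30 and 1.19 in HIP2 but -0.18 in HIP3, below the value of 0.48 in WT4. Of 25 genes of macrophages and other myeloid cells 22 were positive, with a median of 0.73, and Itgam, an integrin of myeloid cells, stood at 8.83 ± 2.19 against 3.30 ± 1.56 CPM. The myeloid list median against the wild-type mean was 1.16 in WT4, above its values of 1.08 in HIP30, 0.86 in HIP2 and 0.26 in HIP3.

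The acute phase, chemokine and myeloid lists passed camera with the preset correlation (limma, Benjamini-Hochberg adjusted p = 1.35e-04, 1.20e-03 and 2.77e-03) and not otherwise, with adjusted p = 0.497, 0.508 and 0.664 with an estimated correlation. Of the 13 acute phase genes 6 had no read in WT26, and without WT26 the mean difference of that list went from 2.42 to 1.18. Without WT26 or WT1 the myeloid list no longer passed camera (adjusted p = 0.157 and 0.066), and its mean difference of 0.60 went to 0.26 and 0.40, and to 1.12 without WT4. The chemokine list did not pass among the libraries numbered 1 to 4 (adjusted p = 0.0564), and its mean difference went from 0.98 to 1.43 without HIP3.

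Markers of islet cells other than beta cells passed camera in the higher direction with the preset correlation only (adjusted p = 0.527 with an estimated correlation). Of 16 tested markers of other islet endocrine cells 15 were positive, with a median of 1.44, but the list median against the wild-type mean ran from -3.35 in WT26 to 3.21 in WT4, wider than the HIP values of 0.90 to 1.39. Ghrl, which encodes ghrelin, stood at 32.4 ± 19.5 CPM in HIP against 10.5 ± 0.0945 CPM in wild type. Ttr, a hormone carrier abundant in islet alpha cells, stood at 139 ± 106 against 19.7 ± 27.1 CPM. Its highest levels were 248 and 134 CPM in HIP30 and HIP2, where the glucagon gene Gcg had no read. Ttr therefore does not mark alpha cells in those libraries. The list passed camera with the preset correlation (limma, adjusted p = 2.77e-03) and not otherwise (adjusted p = 0.527 with an estimated correlation). Of its 16 genes 11 had no read in WT26, and without that library the mean difference went from 1.58 to 0.16 (adjusted p = 0.318). The beta cell list of 10 genes did not pass (camera, adjusted p = 0.842), and its median of -0.12 and mean of 0.15 differed in sign. Its mean was 2.12 without WT4 (adjusted p = 0.0321) and 1.72 without HIP30 (adjusted p = 0.042), but -1.62 without WT26 (adjusted p = 0.104) and -1.09 without HIP3 (adjusted p = 0.556). With an estimated correlation no list passed when a library was left out, and the smallest adjusted p was 0.386 without WT4 and 0.603 without HIP30.

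The immediate early, cholesterol, hypoxia, oxidative phosphorylation and NRF2 lists passed camera in the lower direction with the preset correlation only, where adjusted p = 0.455, 0.534, 0.497, 0.689 and 0.497 with an estimated correlation. The immediate early and oxidative phosphorylation lists had been fixed as lists of RNA quality, and the heat shock list did not pass. The unfolded protein response passed in the higher direction in some settings only, and there with the preset correlation only. Of 23 immediate early genes 17 were negative, with a median of -0.49, and the list median against the wild-type mean was -0.53, -0.46 and -0.37 in HIP30, HIP2 and HIP3. Atf3 and Nr4a1, transcription factors induced by stress, stood at 8.44 ± 6.29 and 6.56 ± 3.92 CPM in HIP against 56.3 ± 39.5 and 20.1 ± 6.24 CPM in wild type. Of 23 cholesterol synthesis genes 21 were negative, with a median of -0.37, and Cyp51, lanosterol demethylase, stood at 420 ± 167 against 677 ± 236 CPM. Of 25 hypoxia and glycolysis genes 18 were negative, with a median of -0.33, among them Pgk1, phosphoglycerate kinase, which differed by -0.87, while Vegfa, the vascular growth factor, differed by 1.34. Of 81 nuclear genes of oxidative phosphorylation 65 were negative, with a median of -0.19, and of 23 genes of the NRF2 response 16 were negative, with a median of -0.20. Gclc and Nqo1, antioxidant enzymes of the NRF2 list, differed by -0.54 and -0.70, whereas Slc7a11 of the same list differed by 1.78.

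These 5 lists passed camera with the preset correlation (limma, Benjamini-Hochberg adjusted p = 2.69e-04, 4.34e-04, 1.89e-03, 1.41e-03 and 0.013 in the order given). None did otherwise, with adjusted p = 0.455, 0.534, 0.497, 0.689 and 0.497 with an estimated correlation. The oxidative phosphorylation list turned to a mean of 0.03 without WT26 (camera, adjusted p = 0.758) and no longer passed without HIP2 (0.144). The hypoxia list was lost without WT26 (camera, adjusted p = 0.0745), where its mean went from -0.29 to -0.16, the cholesterol list without HIP30 (0.0585), where its mean went from -0.38 to -0.17, and the NRF2 list without WT26, HIP2 or HIP3 (0.0924, 0.0582 and 0.0871). The mean of the NRF2 list was -0.18, and ran from -0.23 to -0.10 with libraries left out in turn. The cholesterol list median was 0.16 in HIP3 against the wild-type mean.

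Of the lists about gland epithelium and signalling, 3 passed camera, all with small or unstable differences. Of 9 mucin and trefoil genes 8 were positive, with a median of 0.55, and Agr2, a chaperone of mucin secretion, stood at 412 ± 138 CPM in HIP against 274 ± 51.5 CPM in wild type. Tff1, a trefoil peptide, stood at 297, 287 and 64.3 CPM in WT26, WT1 and WT4, and at 0, 25.6 and 193 CPM in HIP30, HIP2 and HIP3. Of 29 cilium genes 23 were positive, with a median of 0.18, and Pkd2, the calcium channel polycystin, stood at 168 ± 41.2 against 107 ± 6.12 CPM. Of 36 genes of TGF-beta and BMP signalling 22 were negative, with a median of -0.09, and Tgfbi and Smad7 differed by -0.69 and -0.58. Camera with the preset correlation gave adjusted p = 0.0298, 0.014 and 0.0295 for the mucin, cilium and TGF-beta lists (limma, Benjamini-Hochberg), and adjusted p = 0.497 with an estimated correlation for each. The mucin list was lost without WT26, WT4, HIP30 or HIP2 (camera, adjusted p = 0.0924, 0.067, 0.142 and 0.0528), the cilium list without WT26 or HIP2 (0.0839 and 0.0528), and the TGF-beta list without WT1, WT4 or HIP30 (0.121, 0.124 and 0.118). The mean of the TGF-beta list was -0.32, and -0.31, -0.27 and -0.14 without these libraries. The mean of the cilium list was 0.24, and ran from 0.15 to 0.33 with libraries left out in turn.

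**Figure D3:**
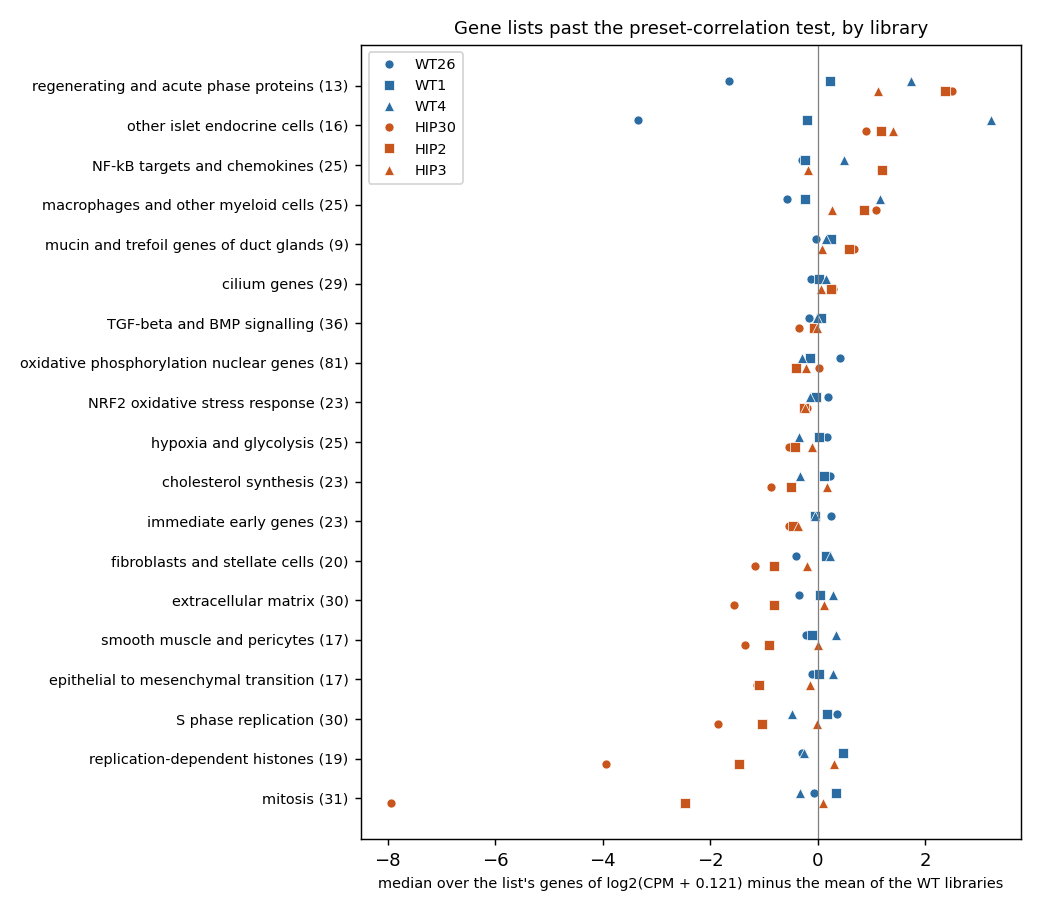
Median difference of each of the 19 gene lists that passed camera with the preset correlation, by library, as log2 of CPM plus 0.121 minus the mean of the wild-type libraries, with the number of tested genes in brackets. Blue symbols are the 3 wild-type libraries and orange symbols the 3 HIP libraries. The mitosis list stands at -7.93 in HIP30, -2.48 in HIP2 and 0.10 in HIP3.

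Bicarbonate transport and lineage genes did not pass as sets with all 6 libraries and the filter used. The list for ion transport of bicarbonate secretion had 11 positive and 10 negative genes with a median of 0.01 (camera, adjusted p = 0.146), but Slc26a9 and Clca1 passed limma's test adjusted over the list alone (adjusted p = 0.016 for each). Over all lists 5 members passed in this way, without a correction for the number of lists. At a filter of 10 CPM in 3 libraries the bicarbonate list passed camera with the preset correlation only (mean 0.71, adjusted p = 0.0229), where the smallest adjusted p of any list = 0.408 with an estimated correlation. Its mean of 0.55 with the main filter ran from 0.19 to 0.77 with libraries left out in turn, and 3 of its 21 genes had no read in WT26. Cftr, the chloride channel of duct cells, differed by 0.57. Duct epithelium, with 8 of 15 genes positive, gave camera adjusted p = 0.505, and the pancreatic and endocrine lineage transcription factors, with 15 of 20 positive, gave 0.0788, which became 0.011 without WT4 (with an estimated correlation no list passed there, at a smallest adjusted p of 0.386). Without WT26, where 4 of its 20 genes had no read, the mean of the lineage list went from 0.45 to 0.11 (adjusted p = 0.301). In the latter list Onecut1, a factor of duct development, differed by 1.06. Stem and progenitor markers, with 9 of 19 genes positive, gave 0.725, and Lgr5, a receptor of epithelial stem cells, stood at 100.3 ± 5.52 CPM in HIP against 58.7 ± 34.5 CPM in wild type.

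The signalling lists gave camera adjusted p = 0.115 for WNT, 0.527 for NOTCH, 0.807 for Hippo and YAP targets, 0.164 for Hedgehog and 0.807 for EGF receptor ligands and growth factors. Wif1, a secreted WNT inhibitor, differed by -1.70, Ctgf, a YAP target, by -2.02, and the NOTCH ligand Dll1 by 1.42, and none passed limma's test (adjusted p = 0.691). With libraries left out in turn Ctgf ran from -2.86 to -1.12 and Wif1 from -2.28 to -1.19, and 72 of the 149 named genes moved over 1.5 times or turned. The unfolded protein response, with 24 of 33 genes positive and a median of 0.15, gave camera adjusted p = 0.0542, and 0.047 and 0.0399 without WT26 and WT1. It passed too with upper-quartile factors (0.0427), library totals (0.0328), a filter of 10 CPM in 3 libraries (0.0236), the number series as a batch term (0.0333) and the deposited values (0.0312). With an estimated correlation no list passed in these settings, and the smallest adjusted p was 0.431, 0.391, 0.408, 0.585 and 0.39 in the order given. Xbp1, its transcription factor, stood at 1481 ± 713 CPM in HIP against 485 ± 320 CPM in wild type. The groups overlapped for Xbp1, with 696 CPM in HIP3 and 832 CPM in WT4. Atf3, the member of this list with the lowest unadjusted p, went the other way, with a log2 difference of -3.03. The p53 targets and apoptosis genes gave 0.0788, and 0.0438 without WT4, and Cdkn1a, the cell cycle inhibitor of that list, stood at 59.8 ± 20.4 against 133 ± 43.3 CPM. Tight and adherens junctions gave 0.247, and 0.0255 without WT4, and their mean of -0.09 ran from -0.22 to -0.0144 with libraries left out in turn. The interferon list gave 0.974, with a median of 0.17 and a mean of 0.04 against a camera statistic in the lower direction. That list passed in the higher direction without WT4 (adjusted p = 6.55e-03) and in the lower direction without WT26 (0.043). These calls with a library left out hold for the preset correlation only, and the smallest adjusted p of any list with an estimated correlation was 0.386 without WT4, 0.593 without WT26 and 0.661 without WT1.

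Among markers of other cells and of RNA quality, the lists without a call were MHC class II antigen presentation (camera, adjusted p = 0.112), acinar cells (0.25), endothelial cells (0.344), lymphocytes (0.146), nerve and Schwann cells (0.593), adipocytes (0.807), intestinal epithelium (0.146), red blood cells (0.225), lymphatic vessels (0.39), heat shock genes (0.646) and cytosolic ribosomal proteins (0.164). Without WT4, camera called the MHC class II list (adjusted p = 2.27e-04), acinar cells (6.20e-03) and lymphocytes (2.05e-03), all higher in HIP, and the ribosomal list lower (0.0255), where the smallest adjusted p = 0.386 with an estimated correlation. Without WT26 the means of the MHC class II, acinar and lymphocyte lists went from 0.46, 0.67 and 0.62 to 0.0207, 0.15 and 0.0442 (adjusted p = 0.898, 0.607 and 0.853). Without WT1, endothelial cells (0.0292), red blood cells (0.0265) and ribosomal proteins (1.78e-03) were called lower and bicarbonate transport higher (0.0427), and the ribosomal list was called lower without HIP30 (7.76e-06) and higher without WT26 (0.047). With an estimated correlation none of these lists passed, and the smallest adjusted p of any list was 0.593 without WT26, 0.661 without WT1 and 0.603 without HIP30. With the number series as a batch term the ribosomal list was called lower (0.0319), where the smallest adjusted p of any list = 0.585 with an estimated correlation. Ccl21, a chemokine of lymphatic endothelium, passed limma's test adjusted over the list alone (adjusted p = 0.0149), at 0.102 ± 0.0935 CPM in HIP against 3.51 ± 2.89 CPM in wild type. The median of the heat shock list was -0.07 and its mean 0.08, and the Hippo list had a median of 0.00206 and a mean of -0.10. Mast cells and mesothelium had 2 and 3 tested genes and were not tested as lists.

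The distances between libraries followed more than the group. The mean Pearson correlation between libraries was 0.921 within groups and 0.904 between groups. The highest pairs were WT1 with HIP3 (0.965) and WT4 with HIP3 (0.965), and the lowest was WT26 with HIP30 (0.805). The first principal component held 56.8% of the variance and placed WT26 at -84.7, WT1 at -44.5, HIP3 at -19.7, WT4 at 7.50, HIP2 at 42.1 and HIP30 at 99.3, so that HIP3 lay between the wild-type libraries WT1 and WT4. In 16 of the 19 lists that passed camera with the preset correlation the HIP3 median lay within the range of the wild-type libraries, and in 17 the mean moved over 1.5 times or turned when a library was left out. None of the 19 passed otherwise, where the smallest adjusted p = 0.455 with an estimated correlation. That value belongs to the immediate early list, whose estimated correlation of -0.00482 lies below the preset 0.01. Correlation between its genes therefore does not account for the loss of that call. Failing in this setting does not show that a list is unchanged. Among the 4 libraries numbered 1 to 4, 8 of the 19 lists no longer passed camera, with adjusted p = 0.22 for mucin, 0.0564 for chemokines, 0.163 for hypoxia, 0.516 for cholesterol, 0.133 for cilium, 0.185 for other islet endocrine, 0.405 for myeloid and 0.102 for oxidative phosphorylation genes. Of the other lists the same 4 libraries gained lymphatic vessels in the lower direction (mean -0.89, adjusted p = 0.0421) and interferon, where the smallest adjusted p of any list = 0.742 with an estimated correlation. Without a filter on low counts camera lost the mucin and TGF-beta lists (adjusted p = 0.154 and 0.0589), and at a filter of 10 CPM in 3 libraries the chemokine list (adjusted p = 0.10).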

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

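The deposited log2 values as they stand, a pseudocount of 0.5 CPM and the libraries numbered 1 to 4 alone were added after seeing the data. No gene passed an adjusted p of 0.05 in any alternative or of 0.10 in limma's main test; the smallest adjusted p was 0.0882, without HIP3. Unadjusted counts were 154 in libraries 1 to 4 and 2388 with sample quality weights, against 792. Lists past camera numbered 13 to 26, against 19, and 9 passed in every setting with the preset correlation. With an estimated correlation 0 passed, and by fry 0, also in its mixed form. The estimated correlations ran from -0.0997 for adipocytes to 0.939 for mitosis. Left-out libraries gave 15 to 26 lists, libraries 1 to 4 gave 13 of which 11 were among the 19, and the batch term gave 21. Of 149 tested named genes 140 kept their sign throughout, and of 44 lists 31 kept the sign of their mean. Most named genes were chosen by low p in these same libraries, which favours a stable sign, so the count of genes does not measure robustness. The share of higher genes at an unadjusted p under 0.05 ran from 35.6% to 58.6%. The difference between correlations within and between groups was 0.0177, 0.0202 with a prior of 0.5 reads and 0.011 by Spearman.

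Sign changes follow as log2 values, and the cause was not tested. Pdx1 was 0.0285 with library totals, 0.0286 with the deposited values, 0.024 in libraries 1 to 4 and 0.00285 with quality weights, where Ins1 was 0.0481, Ins2 0.22, Hba2 0.33 and the EGF list 0.0921. The stem list was 0.0188 with library totals and 0.0198 with deposited values. The mucin list was -0.0328 without a filter and -0.17 at 10 CPM, where the interferon, nerve and adipocyte lists were -0.0279, -0.38 and -0.22. In libraries 1 to 4, Ikzf1 was -0.29, Cd4 -0.19, and the interferon list -0.41 (camera, adjusted p = 2.75e-04; smallest adjusted p = 0.742 with an estimated correlation), MHC class II -0.15, beta cell -0.0525 and lymphocyte -0.0283.

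With libraries left out in turn, ranges were -0.11 to 0.00475 for Pdx1, -4.35 to 3.94 for Ins1, -3.79 to 3.55 for Ins2, -3.12 to 2.45 for Iapp, -1.84 to 0.25 for Gjd2, -1.02 to 0.18 for Hba2 and -0.0356 to 0.85 for Ero1lb. List means ranged from -0.0288 to 0.30 (mucin), -0.22 to 0.10 (stem), -0.21 to 0.0856 (EGF), -0.29 to 0.52 (interferon), -1.62 to 2.12 (beta cell), -0.43 to 0.0648 (endothelial), -0.00697 to 0.79 (nerve), -0.0371 to 0.16 (heat shock), -0.26 to 0.14 (ribosomal) and -0.28 to 0.0273 (oxidative phosphorylation).

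No paired analysis was possible because the groups share no replicate numbers. The planned DESeq2 and exact tests on counts were not run, and limma-voom on the recovered reads was. With 3 libraries a group, differences of genes near 0 reads are limited by the pseudocount.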

Other observations

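All tests in this part were chosen after the values they concern had been seen. Some abundant genes had no read in 1 library only, and the genes named here were chosen after their values were seen. In HIP30 these included Cd59, a complement inhibitor, with 12328 reads in HIP2 and 31925 to 74774 in the other libraries, and Fn1, the matrix protein fibronectin, with 5295 reads in HIP2 and 12882 to 65828 elsewhere. In WT26 they included Mpeg1, a macrophage perforin, with 2949 reads in WT1, 3038 in WT4, 31739 in HIP30, 31862 in HIP2 and 2352 in HIP3. Reg3g, a secreted antibacterial lectin, had 0 reads in WT26, 227 in WT1, 1048 in WT4 and 343 in HIP3, but 8898 in HIP30 and 7058 in HIP2, and Sst, which encodes somatostatin, had 0, 450, 576, 166, 4047 and 2814 reads in the same libraries. Of 160 genes unread in HIP30 with over 5 reads in each of the other 5 libraries, HIP2 was the lowest of the remaining libraries for 139, or 86.9%, and of 171 genes unread in WT26 under the same cut, WT1 was the lowest for 124, or 72.5%, where an equal share would be 20%.

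The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 792 genes and the highest of the others 2363, and 3 splits gave at least the real count. That highest split set WT26, WT1 and HIP3 against WT4, HIP30 and HIP2 and points to a structure of the samples other than the groups. At an adjusted p under 0.05 the real split and all others gave 0 genes, so 10 of 10 splits are as large. A count of 0 in the real split fixes that outcome in advance, and it decides nothing. For lists past camera the real split gave 19 and the highest other 19, reached by 2 splits with the real split counted.

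The absence of mitosis genes in HIP30 and their low level in HIP2 was set against technical sources and the HIP genotype. A differing mix of captured cells between libraries was not tested as a source. Random loss of single transcripts from little RNA is argued against. In HIP30 67.7% of the mitosis list had no read, while the highest of 10000 random lists matched on wild-type level reached 12.9%. Those lists model genes lost independently and cannot address genes lost together, as when a capture misses the cells that express them. Carry-over of reads into HIP2 from the other libraries numbered 1 to 4 stays open. The median HIP2 level of mitosis genes was 5.27% of the reads in WT1, WT4 and HIP3 together, with quartiles of 4.26% to 9.16%. That of the 139 other genes among the 160 unread in HIP30 was 5.86%, with quartiles of 4.26% to 9.92%. Carry-over would give a near constant share, and these quartiles are too wide for that, but the sets do not lie apart either. The HIP2 share of 2.16% of WT4 and HIP3 reads for genes unread in WT26 and HIP30, with quartiles of 1.14% to 3.59%, lies lower and goes against carry-over. That share does not measure carry-over from WT1. The mitosis median of HIP3 was 0.10 against the wild-type mean, within the wild-type range of -0.34 to 0.33, which goes against the HIP genotype as the source, but 1 library cannot exclude it and it stays open. Genes unrelated to division such as Cd59 and Fn1 were at 0 in HIP30 and lowest of the others in HIP2 too, and the mitosis list made up 21 of the 160 genes.

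Insulin transcripts were abundant in WT4 and HIP3 alone. Neighbouring islet and acinar tissue taken with the glands is a candidate source, since 17 of 26 acinar genes were higher in both WT4 and HIP3 than in every other library. If the libraries were exchangeable, 1.73 would be so. WT4 and HIP3 also had the fewest genes without a read, 672 and 1837 against 2155 to 2822 elsewhere. The share over other genes is not given here, so the excess alone does not settle the source. Among the most abundant, Cel had 167 and 561 reads and Ctrb1 298 and 327 reads in WT4 and HIP3, against 127647 and 60667 reads of Ins1. Whole islets cannot be told apart from other sources, since Gcg had 0.69 reads per 10000 reads of Ins1 in these libraries and no table here gives that ratio for an islet. The pattern did not follow the genotype, since each group holds 1 of these libraries.

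Genes without a read in WT26 or HIP30 and with over 5 reads in each of the other 5 libraries numbered 171 and 160, against 2 in WT1 and 0 in WT4, HIP2 and HIP3. Library depth is argued against, since after thinning to equal totals 166 and 155 such genes were left and at most 4 in another library. Exchange of reads among the 4 libraries numbered 1 to 4, which could leave a trace of every transcript in each, would give a near constant share. The share of WT4 and HIP3 reads for genes unread in WT26 and HIP30 had a median of 0.785% in WT1 and 2.16% in HIP2, with quartiles 3.05-fold and 3.13-fold apart, which goes against exchange, but traces of tissue and low counts widen such shares too and it stays open. A batch of the libraries numbered 26 and 30 cannot be told apart from differences between single captures, with 1 library of each group in that series.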
